A study of Homo sapiens with 12 samples.

How the data were processed

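Total RNA of U251 glioblastoma cells was prepared with the mirVana kit after transfection of ON-TARGETplus SMARTpool siRNA with DharmaFECT 2, each siRNA at 50 nM, and biotin-labelled cRNA was hybridized to Affymetrix GeneChip expression arrays, 1 array per sample. The 12 arrays fell into 4 groups of 3: control siRNA, ETV6 siRNA, NFKB1 siRNA, and both siRNAs. The deposited values are log2 probe set levels made by the authors; how background, summarization, normalization and the choice of probe sets were done is not given in the sources used here. The upper quantiles of the arrays were nearly equal and the medians were not. No 2 arrays held identical values (0 pairs), and 0 columns of values per sample were left unused.

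Gene symbols came from the probe table of the platform, which named 18176 probe sets. Of the probe sets 17313 named 1 gene, 857 several and 1293 none, beside 57 control probe sets, among them 18 for hybridization and 24 for poly-A spike-ins. Entrez identifiers of 17307 matched the RefSeq gene table of the human assembly GRCh38.p14, used for names only, and 0 symbols needed an update. No genome build is named for the values, so no coordinates are given. For each gene the probe set with the highest mean over all arrays was used, which left 10346 genes, 4482 of them with over 1 probe set. Genes with a mean under the 25th percentile (log2 7.54) were left out, except that the 2 targeted genes were kept whatever their level, which mattered for NFKB1, and 7760 were tested.

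One linear model with a mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 8 residual and 3.41 prior degrees of freedom). It gave 7 comparisons: each knock-down against control, each pair of knock-downs, and the interaction, which is double minus ETV6 minus NFKB1 plus control. Tests were two-sided, p-values were adjusted by Benjamini and Hochberg over the genes of a comparison, and an adjusted p under 0.05 was called. An exact permutation test of 3 arrays against 3 cannot give a p below 0.1, so it was not used for single genes. The groups, tests, gene lists, naming rule and first set of alternatives were chosen before the data were examined. The fit was tried on simulated data of 7760 genes with 100 changed per fold size. For ETV6 siRNA against control it recovered 93% of 1.5-fold and 99% of 2-fold changes (5.9% false among calls). The shares were 90% and 98% for NFKB1 siRNA (5.5% false), and 93% and 98% for double siRNA (6.8% false). The simulated noise was independent between genes and had the same spread in all groups. No direction shared by many genes was simulated, so these shares need not hold for the real calls.

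Of 20 gene lists fixed in advance 19 had at least 3 tested members and were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, with ETV6 and NFKB1 left out. The list of epithelial, immune, endothelial and neuronal markers had 1 tested member and was not tested. Camera with an estimated correlation was an alternative. Counts of changed members are given over all genes tested and adjusted over the list alone.

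Genes were named by a rule. ETV6 and NFKB1 were always named. For each comparison with control the 8 highest and 8 lowest called log2 changes were named among genes whose 3 arrays all lay above or all below the 3 control arrays, leaving out names without annotation. Up to 4 members with the smallest adjusted p were named for each list described, and the 4 highest and 4 lowest for the interaction and for comparisons between knock-downs. Genes outside this rule are said to be named after their values were seen.

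The alternatives were shifting each array to the same median, quantile normalization, no filter, a filter at the 50th percentile, the mean of a gene's probe sets, every probe set on its own, array weights, eBayes with trend and robust variances, fry in place of camera, a fit of only the groups compared, a replicate block, and leaving out each array in turn. Fry tests each list against no change and not against the other genes, so it is not among the 25 alternatives counted for lists. Leaving out an array leaves 2 in its group, whose spread is pooled over the groups. After the data were seen, 2 more were added: leaving out both control siRNA replicate 3 and ETV6 siRNA replicate 2, and a covariate. The covariate is the position of each array along the difference between control siRNA replicate 3 and the mean of control replicates 1 and 2. It is built from a control array's own values and is nearly confounded with double siRNA, so a call lost with it is no evidence that a gene did not change. Within groups mainly control siRNA replicate 3 varies along it, and the double siRNA arrays lie beyond that array. A call kept with it for double siRNA thus rests on an extrapolation. Overlaps between comparisons that share the control arrays were set beside 20 simulations of unchanged groups. All groups, the control included, were drawn from each gene's spread in that group, independently between genes. A direction shared by many genes, such as that of control siRNA replicate 3, was thus not simulated. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.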

Results

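Gene expression was measured in U251, an established human glioblastoma cell line, after small interfering RNA (siRNA) against ETV6, NFKB1 or both. ETV6 encodes a transcriptional repressor of the ETS family, and NFKB1 encodes the p105 precursor of the NF-kB subunit p50. The 12 arrays formed 4 groups of 3: control siRNA, ETV6 siRNA, NFKB1 siRNA, and both siRNAs together (here called double siRNA). Each array gave log2 probe set levels, between 3.05 and 14.75 over the table, and the group means of the array medians lay between 8.16 and 8.35. The number of arrays limits the precision of each value. Nothing in the labels says that the 3 arrays of a group came from separate cultures, so p-values measure the spread between these samples only, which may be technical.

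The targeted genes were examined first, in every array. ETV6, on the brighter of its 2 probe sets, had a log2 level of 8.87 ± 0.26 (SD, n = 3) in control cells and fell to 6.73 ± 0.11 with ETV6 siRNA, which left 22.6% of the control level (limma, adjusted p = 7.48e-07). With double siRNA it fell to 7.36 ± 0.08, or 35.1% of control (adjusted p = 1.24e-06), a smaller decrease than with ETV6 siRNA alone (log2 difference 0.64, SE 0.11, adjusted p = 0.000157). The second ETV6 probe set read 5.03 to 5.29 and 5.73 to 5.94 in the same groups against 7.36 to 7.59 in control cells. Those levels lay below the 5th percentile of their arrays (5.74 to 5.97 and 6.15 to 6.16), so no share is given. With NFKB1 siRNA the first ETV6 probe set was at 8.70 ± 0.05 and did not pass the test (adjusted p = 0.206), and the second was at 132.3% of control. NFKB1, with a single probe set in the table, was at 7.32 ± 0.15 in control cells and fell to 6.59 ± 0.47 with NFKB1 siRNA, 60.3% of control (adjusted p = 0.00691; 0.0524 with only the groups compared and, at -0.564, 0.114 with the covariate described below, neither called). It fell to 6.55 ± 0.05, 58.8% of control, with double siRNA (adjusted p = 0.00165), which was not called with the covariate either. With ETV6 siRNA NFKB1 was at 7.81 ± 0.06, 141.2% of control, which did not pass (adjusted p = 0.104). NFKB1 siRNA replicate 3, at 6.05, lay below replicates 1 and 2 at 6.95 and 6.75. Without that array NFKB1 was called higher with ETV6 siRNA (0.50, adjusted p = 0.00384) and lower with double than with NFKB1 siRNA (-0.30, adjusted p = 0.00729), and its decrease with NFKB1 siRNA was -0.46. Without control siRNA replicate 3 the first ETV6 probe set was called lower with NFKB1 siRNA (-0.32, adjusted p = 0.00329).

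**Figure D1:**
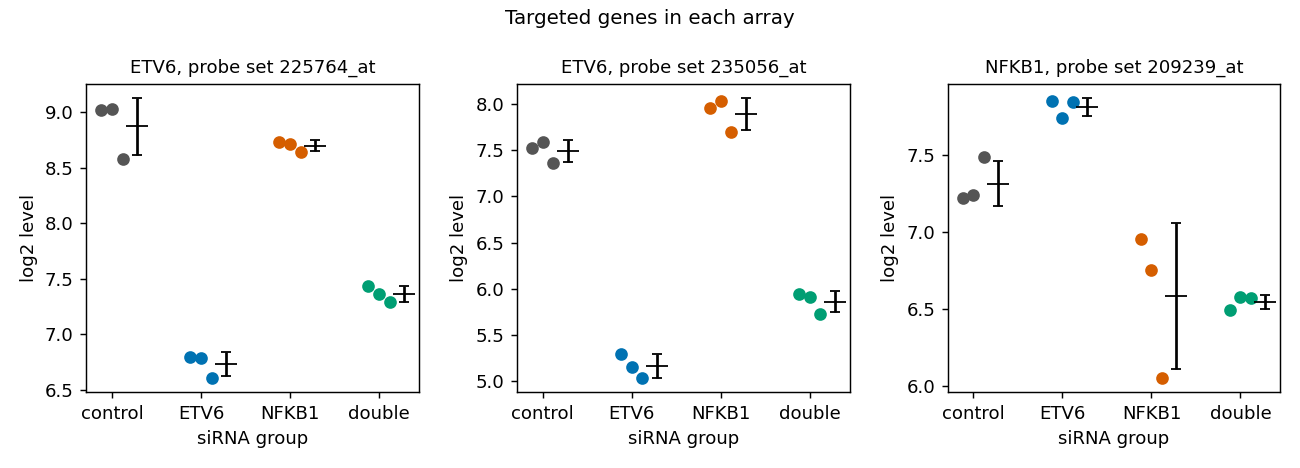
Log2 level of the targeted genes (y axis) in each array of the 4 siRNA groups (x axis); points are arrays, the bar beside them is the group mean with its SD (n = 3). ETV6 averaged 6.73 with ETV6 siRNA and 7.36 with double siRNA against 8.87 in control cells on its first probe set, and NFKB1 averaged 6.59 and 6.55 with NFKB1 and double siRNA against 7.32.

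The comparison of ETV6 siRNA with control siRNA asked what follows from knocking down ETV6 alone. HMOX1, which encodes the heme-degrading enzyme heme oxygenase 1, rose 2.57-fold, from 9.96 ± 0.06 to 11.33 ± 0.06 (SD, n = 3, adjusted p = 1.33e-07), and was the only one of the 340 genes that rose to pass 2-fold. The next largest rises were those of ACKR3, a chemokine scavenging receptor, at 1.64-fold, SGPL1, the sphingosine-1-phosphate lyase, at 1.63-fold, and the kinase gene PAK6 at 1.62-fold. CHI3L1, a secreted glycoprotein and mesenchymal glioblastoma marker, rose 1.6-fold, the chemokine gene CCL2 1.57-fold, the histone gene H2BC12 1.55-fold and GALNT17 1.52-fold. Among genes that fell, CITED1, a transcriptional co-activator, fell 2.28-fold from 11.78 ± 0.08 to 10.59 ± 0.03 (adjusted p = 4.39e-07), and CXCL8, which encodes the neutrophil chemokine interleukin 8, fell 2.19-fold (adjusted p = 0.00143). LRRC58 fell 3.05-fold, the kinetochore motor gene CENPE 2.51-fold, SPOPL 2.38-fold, PI15 2.28-fold, the chromatin remodeller gene HELLS 2.2-fold and PHIP 2.18-fold.

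In all, 827 of 7760 genes changed with ETV6 siRNA (limma, Benjamini-Hochberg adjusted p under 0.05), 340 higher and 487 lower, and 102 of them by over 1.5-fold, 10 higher and 92 lower. Of the 39 changed genes named under the naming rule, 12 lost the call when some single array was left out. PI15 was the only one of them among the largest changes (log2 change -1.05, adjusted p = 0.114 without ETV6 siRNA replicate 3, and -1.15, 0.101 without replicate 1; -0.53, 0.078 as the mean of its 2 probe sets, of which the other gave 0.13), and over the alternatives its log2 change lay between -1.47 and -0.53. The count itself was 436 without ETV6 siRNA replicate 1, 469 without ETV6 siRNA replicate 3, 187 with only these 6 arrays in the fit and 2342 with array weights.

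Of 25 tested G2/M genes, those expressed toward mitosis, 12 fell with ETV6 siRNA and none rose (21 fell adjusted over the list alone), with a median log2 change of -0.28. The camera adjusted p was 8.89e-13 with the preset correlation between genes of 0.01, and the adjusted p was 0.193 with an estimated correlation. CENPE fell by 1.33 on the log2 scale, the spindle motor gene KIF11 fell by 0.67, the mitotic kinase gene AURKA fell by 0.32 and KIF20A fell by 0.26. Of 24 G1/S genes, 9 fell and none rose (13 fell adjusted over the list alone; median log2 change -0.18, camera adjusted p = 1.14e-08, and adjusted p = 0.285 with an estimated correlation), among them CCND1, which encodes cyclin D1, at -0.61 ± 0.11 (SE), the ribonucleotide reductase genes RRM1 at -0.46 and RRM2 at -0.29, and the replication helicase gene MCM6 at -0.32. The second probe set of RRM1 gave 0.13. Of 14 DNA repair genes 5 fell and none rose (5 adjusted over the list alone; camera adjusted p = 0.0203, and adjusted p = 0.366 with an estimated correlation), with BRCA1 at -0.66 ± 0.12 and the checkpoint kinase gene CHEK1 at -0.60 ± 0.09 (SE). The second probe set of BRCA1 gave -0.02, and the 3 of CHEK1 ran from -0.60 to -0.23. Over the other 24 alternatives the adjusted p stayed at or below 3.38e-07 for G2/M and 1.7e-05 for G1/S, while the DNA repair call was lost in 5 of them, with 0.162 without control siRNA replicate 3 as the highest.

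Smaller shifts were seen in 3 further lists. Of 22 hypoxia and glycolysis genes 5 rose and none fell (8 rose adjusted over the list alone; camera adjusted p = 0.00727, and adjusted p = 0.366 with an estimated correlation), with PFKFB4, a regulator of glycolysis, at 0.33 ± 0.06 and the prolyl hydroxylase gene EGLN3 at 0.39 ± 0.09 (SE). EGLN3 was at 0.38 with an adjusted p of 0.052 without ETV6 siRNA replicate 1. The adjusted p of this list was 0.149 without control siRNA replicate 1 and 0.0846 with array weights, and as low as 0.00174 without control siRNA replicate 3. Of 9 astrocyte markers 2 fell (4 adjusted over the list alone), GFAP at -0.30 ± 0.08 and FABP7 at -0.15 ± 0.04 (SE), with a camera adjusted p of 0.0498 (adjusted p = 0.285 with an estimated correlation). Of 22 extracellular matrix genes 5 rose and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 0.0498, and 0.604 with an estimated correlation), with the matrix protease gene MMP14 at 0.28 ± 0.06 and the fibrillin gene FBN1 at 0.33 ± 0.07 (SE). Those last 2 calls did not hold in general: the call was lost in 16 and 17 of 25 alternatives respectively, and GFAP (0.127 without ETV6 siRNA replicate 3), FABP7 (0.14 without ETV6 siRNA replicate 2) and FBN1 (0.0559 without ETV6 siRNA replicate 1) lost theirs too. Among single arrays left out, the highest adjusted p of the list was 0.186 for astrocyte markers and 0.419 for extracellular matrix genes, both without control siRNA replicate 3, and the lowest over all alternatives were 0.0107 and 0.000726.

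The NF-kB and ETS gene lists did not shift as groups with ETV6 siRNA. Of 10 NF-kB target genes 1 rose, CCL2 at 0.65 ± 0.10, and 1 fell, CXCL8 at -1.13 ± 0.16 (SE; 1 and 1 adjusted over the list alone), and the camera adjusted p was 0.126. None of 8 NF-kB subunit and regulator genes passed (none adjusted over the list alone; adjusted p = 0.583). Of 13 other ETS family genes 2 fell, ELF1 at -0.76 ± 0.10 and ELK3 at -0.33 ± 0.07 (SE; 2 adjusted over the list alone), and the list had an adjusted p of 0.0766, which ranged from 0.0469 without control siRNA replicate 2 to 0.494 over the alternatives. ELK3 was at -0.29 with an adjusted p of 0.0522 without ETV6 siRNA replicate 3.

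The comparison of NFKB1 siRNA with control siRNA asked the same for NFKB1. HMOX1 again rose most, 2.21-fold to 11.11 ± 0.02 (adjusted p = 4.58e-07). PFKFB4 rose 2.02-fold, from 10.69 ± 0.07 to 11.70 ± 0.06 (SD, n = 3, adjusted p = 7.31e-07), ANKRD37, a hypoxia-induced ankyrin repeat gene, rose 2.01-fold, MIR210HG, the host transcript of the microRNA miR-210, 1.89-fold, and HILPDA, a lipid droplet gene, 1.87-fold. SCUBE3 rose 1.78-fold, ZNF395 1.73-fold and the phosphatase gene PTPRO 1.7-fold. The largest decreases were those of BCAT1, the cytosolic branched-chain aminotransferase, which fell 4.55-fold from 9.72 ± 0.34 to 7.53 ± 0.13 (adjusted p = 2.99e-06), NAPG at 3.95-fold, the centrosomal gene NIN at 3.45-fold, LRRC58 at 3.34-fold and DICER1, the microRNA-processing nuclease, at 3.18-fold. HELLS fell 3.15-fold, PI15 3.03-fold and CD2AP 2.94-fold. The second probe set of NAPG gave a log2 change of 0.06 against -1.98, and that of PI15 -0.06 against -1.60. The 4 probe sets of BCAT1 ran from -2.27 to -0.21 and the 3 of NIN from -1.79 to -0.36.

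In all 3148 of 7760 genes changed with NFKB1 siRNA, 1200 higher and 1948 lower, of which 28 and 607 by over 1.5-fold. The split depended on the array scaling: 38.1% of the called genes were higher with the deposited values, 62.2% (2429 of 3905) with each array shifted to the same median and 57.5% (2192 of 3812) after quantile normalization. The count was 5136 when every probe set was tested, 1855 with only these 6 arrays in the fit and 1617 with the covariate chosen after seeing the data.

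Of 22 hypoxia and glycolysis genes 15 rose with NFKB1 siRNA and none fell (16 adjusted over the list alone), with a median log2 change of 0.33 and a camera adjusted p of 8.3e-08. The adjusted p was 0.139 with an estimated correlation and between 2.87e-13 and 2.31e-05 over the other 24 alternatives. Beside PFKFB4 at 1.02 ± 0.06 and ANKRD37 at 1.01 ± 0.08, the stress gene NDRG1 was at 0.62 ± 0.06 and the collagen prolyl hydroxylase gene P4HA2 at 0.53 ± 0.05 (SE). The same list had a median of 0.07 with ETV6 siRNA and 0.12 with double siRNA.

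The tested NF-kB target genes did not fall as a group with NFKB1 siRNA: of 10, 2 rose and 2 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.519). Of the 30 genes of that list 15 had a usable probe set and 10 were tested, and NFKB1 RNA was left at 60.3% of control. Whether the other members, or a deeper knock-down, would show a decrease was not tested. TNIP1, an inhibitor of NF-kB signalling, was at 0.51 ± 0.06 and the cytokine gene IL6 at 0.37 ± 0.08, while CCL2 was at -0.54 ± 0.10 and the urokinase gene PLAU at -0.40 ± 0.06 (SE). None of 8 NF-kB subunits and regulators passed (none adjusted over the list alone; adjusted p = 0.958), with RELA, the p65 subunit gene, at 0.17 ± 0.10 and CHUK, a kinase gene of the IKK complex, at -0.36 ± 0.14 (SE). Of 13 ETS family genes 7 fell and 1 rose (8 and 2 adjusted over the list alone), with ELK3 at -1.12 ± 0.07, ELF1 at -0.88 ± 0.10, FLI1 at -0.57 ± 0.12 and ETS1 at -0.33 ± 0.07 (SE). With the covariate ETS1 was at -0.158 (limma, adjusted p = 0.0816) and lost its call. The camera adjusted p of this list was 0.074 and ranged from 0.0282 with each array shifted to the same median to 0.645 with an estimated correlation; it was 0.0487 without control siRNA replicate 3.

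**Figure D2:**
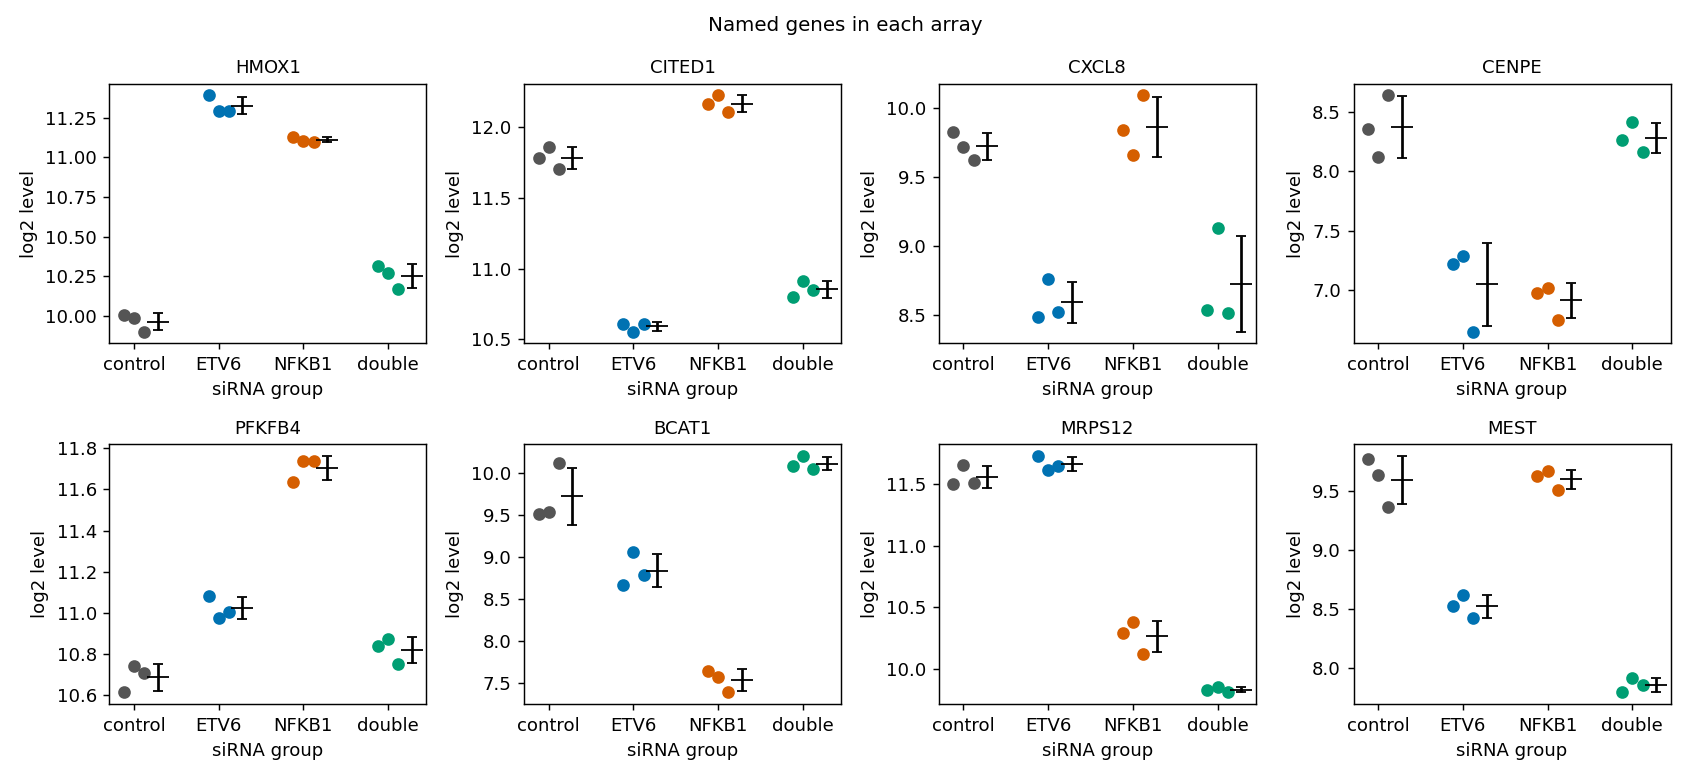
Log2 level (y axis) of 8 named genes in each array of the 4 siRNA groups (x axis); points are arrays and the bar beside them is the group mean with its SD (n = 3). HMOX1 averaged 11.33 and 11.11 with the single siRNAs against 9.96 in control cells and 10.25 with double siRNA, and CITED1 averaged 10.59 and 10.85 in the groups with ETV6 siRNA against 11.78 in control cells.

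Both single knock-downs changed many genes the same way. HMOX1 rose and LRRC58, CENPE, HELLS and PI15 fell in both, and 177 genes were called higher and 340 lower in both comparisons, with 90 called in opposite directions. Independent lists of these sizes would share 52.6 and 122.3 genes. Unchanged groups simulated with a simulated control in common shared 5.6 and 5.35 on average over 20 simulations. No gene was changed there, so these counts do not tell what lists of the observed sizes would share through the controls. Genes were drawn independently there, so a deviation of a control array that many genes share was not simulated. The correlation of the fold changes across genes was 0.518 against 0.728 in the simulation, and their covariance was 0.0303 against 0.0099. Part of the excess may come from the shared controls, since 3 control arrays cannot be split into sets of at least 2. The number called the same way was 263 without ETV6 siRNA replicate 1, 285 without ETV6 siRNA replicate 3, 1144 with array weights and 115 with only the groups compared in each fit.

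The direct comparison of ETV6 siRNA with NFKB1 siRNA separated genes that followed each siRNA. CITED1 was 2.98-fold lower with ETV6 siRNA (adjusted p = 3.79e-08), CXCL8 2.42-fold lower, MEST, a paternally expressed imprinted gene, 2.11-fold lower and the spindle checkpoint gene MAD2L1 2.09-fold lower. NAPG was 3.32-fold higher with ETV6 siRNA than with NFKB1 siRNA, the fatty acid ligase gene ACSL4 3.13-fold, the RNA-binding protein gene RBM24 2.84-fold and HAPSTR1 2.78-fold. In all 2709 genes differed, 1695 higher and 1014 lower with ETV6 siRNA. That split, 62.6% higher, became 37.6% (1246 of 3317) with each array shifted to the same median and 45% (1426 of 3166) after quantile normalization. The count was 1665 without ETV6 siRNA replicate 2.

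The comparison of double siRNA with control siRNA asked what knocking down both genes does. MEST fell 3.34-fold, from 9.59 ± 0.21 to 7.85 ± 0.06 (SD, n = 3, adjusted p = 7.67e-07), MRPS12, a mitochondrial ribosomal protein gene, 3.3-fold (adjusted p = 1.66e-07) and MICALL1, an endosomal recycling gene, 2.93-fold. The nucleolar gene NOL6 fell 2.51-fold, the sphingosine kinase gene SPHK1 2.5-fold, the imprinted gene PHLDA2 2.35-fold, the ribosome biogenesis gene GRWD1 2.34-fold and CCND1 2.34-fold. The largest increases were those of OGFRL1 at 5.23-fold, from 8.31 ± 0.48 to 10.70 ± 0.09, SOX2-OT, a long noncoding transcript that overlaps SOX2, at 4.86-fold, the RNA-binding protein gene TIA1 at 4.48-fold and LIN7C at 4.46-fold. The microtubule-associated kinase gene DCLK1 rose 4.28-fold, EEIG2 4.26-fold, DPY19L4 4.23-fold and the long noncoding transcript MIR100HG 4.22-fold. The log2 changes of the 3 probe sets of OGFRL1 ran from 0.45 to 2.39, and the 2 of DCLK1 gave 0.68 and 2.10.

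In all 6274 of 7760 genes differed, 2473 higher and 3801 lower, of which 1284 and 1075 by over 1.5-fold. The double siRNA arrays also stood apart in measures that do not depend on the genes compared. The poly-A spike-in probe sets, which report RNA added during sample preparation, lay between 7.97 and 8.05 on the log2 scale against 8.37 to 9.35 in the other 9 arrays. The difference between the 3' and 5' probe sets of ACTB, a sign of RNA or cRNA length, was 2.05 to 2.16 against 1.52 to 1.91, and the Alu repeat probe set was at 14.36 to 14.46 against 14.04 to 14.20 (exact permutation test of 3 arrays against 9, two-sided, p = 0.00455 and adjusted p = 0.00682 over 6 measures for each of these 3). The array median differed too (8.34 to 8.38 against 8.08 to 8.28, the same p), and the hybridization spike-ins overlapped (10.66 to 10.92 against 10.83 to 11.35, adjusted p = 0.0163). The 3' minus 5' difference of GAPDH, at 0.457 to 0.51, lay within the range of the other arrays, 0.374 to 0.538 (exact permutation test, p = 0.341). Control siRNA replicate 3 deviated from the other 2 control arrays in the direction in which double siRNA differed from NFKB1 siRNA, with a correlation of 0.854 across 7760 genes (Spearman 0.812), between arrays that are not shared; genes are not independent replicates. With each array's position along that direction as a covariate, chosen after seeing the data, 314 genes were called, 278 of them also called the same way before, while the median standard error of the double siRNA change rose from 0.07 to 0.16. MRPS12 at -1.60 (adjusted p = 0.00553), MEST at -1.25 (0.0147), PHLDA2 at -1.15 (0.0392), MIR100HG at 1.10 (0.0396), LIN7C at 0.92 (0.0345) and DPY19L4 at 0.81 (0.0267) were among those called with it, and OGFRL1 at 0.86 (0.0766), TIA1 at 0.62 (0.111) and NOL6 at -0.41 (0.202) were not.

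**Figure D3:**
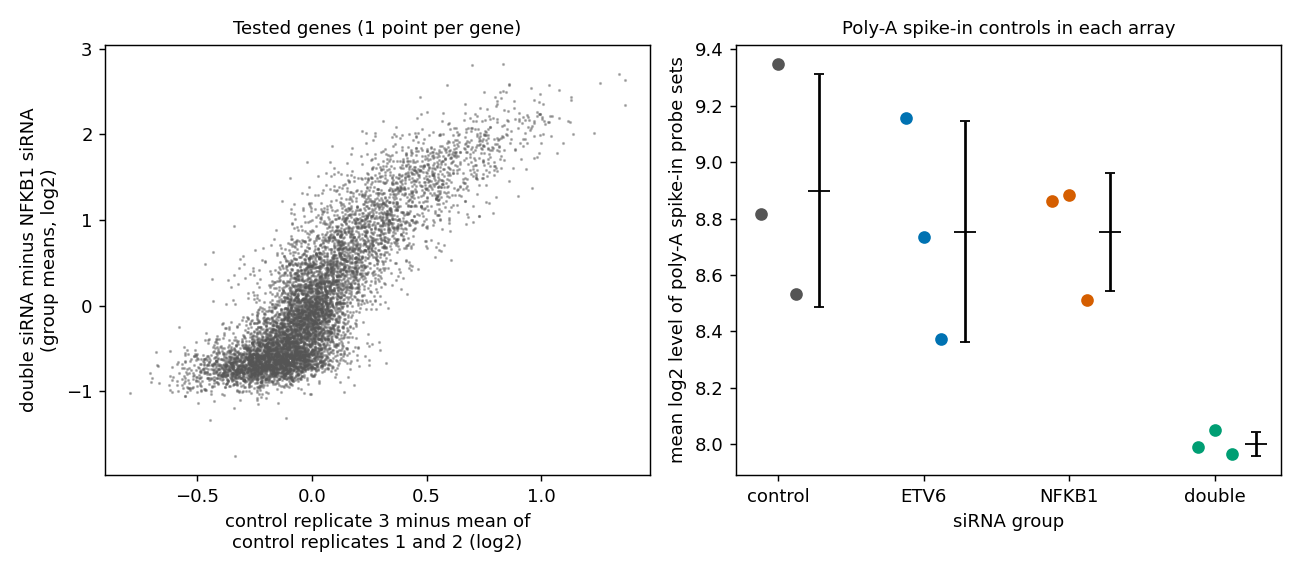
Left, for each tested gene (points), the mean log2 level with double siRNA minus that with NFKB1 siRNA (y axis) against control siRNA replicate 3 minus the mean of control replicates 1 and 2 (x axis, log2), with a correlation of 0.854 across genes. Right, the mean log2 level of the poly-A spike-in probe sets (y axis) in each array by siRNA group (x axis), with the group mean and SD (n = 3) beside the points; the double siRNA arrays lay between 7.97 and 8.05 and all others at 8.37 or above.

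The median change of all genes with double siRNA was -0.13 on the log2 scale, and it was -0.24 with each array shifted to the same median and -0.19 after quantile normalization. Against that shift, 18 of 24 G1/S genes fell and 1 rose (the same counts adjusted over the list alone; median -0.49, camera adjusted p = 0.0276, and adjusted p = 0.921 with an estimated correlation). The replication licensing gene CDT1 was at -1.22 ± 0.10, the helicase genes MCM5 at -1.01 ± 0.07 and MCM2 at -0.90 ± 0.07, and the chromatin assembly gene CHAF1B at -0.99 ± 0.06 (SE). Of 25 G2/M genes 16 rose and 4 fell (the same adjusted over the list alone; median 0.29, adjusted p = 0.0306, and 0.921 with an estimated correlation), with cyclin A2 (CCNA2) at 0.81 ± 0.06 and KIF23 at 0.79 ± 0.09, and with CDC20 at -0.46 ± 0.05 and AURKB at -0.56 ± 0.06 (SE). The second probe set of AURKB gave 0.20. Of 22 hypoxia and glycolysis genes 10 rose and 2 fell (7 and 1 adjusted over the list alone; adjusted p = 0.0448, and 0.921 with an estimated correlation), with the pyruvate dehydrogenase kinase gene PDK1 at 1.79 ± 0.14, the mitophagy receptor gene BNIP3L at 1.64 ± 0.17, P4HA1 at 1.15 ± 0.09 and the histone demethylase gene KDM3A at 0.93 ± 0.08 (SE). The 2 probe sets of PDK1 gave 0.51 and 1.79. Over the other alternatives the adjusted p reached 0.0577 for G1/S, 0.922 for G2/M with the covariate (median 0.01; 0.0616 with no filter and 0.0545 with the 50th percentile filter, neither called) and 0.134 for hypoxia and glycolysis with array weights. The hypoxia call was also lost without control siRNA replicate 1 (0.0552), control siRNA replicate 3 (0.0707) or double siRNA replicate 2 (0.069), and in 10 of 25 alternatives in all; with each array shifted to the same median the list had a median of 0.011 (0.121). With the covariate the hypoxia and glycolysis list (median 0.144) and the G1/S list (median -0.23) kept their call (camera adjusted p = 0.00832 for each). As single genes, none of the 22 hypoxia and glycolysis genes and 3 of the 24 G1/S genes were called with it. Named genes that lost their call with the covariate included PDK1 at 0.762 (limma, adjusted p = 0.0532), P4HA1 at 0.717 (0.0663), BNIP3L at 0.28 (0.253), KDM3A at 0.301 (0.115), CDT1 at -0.641 (0.0841), KIF23 at 0.436 (0.233), CDC20 at -0.276 (0.197) and AURKB at -0.324 (0.164). Of the 39 genes named by the rule for this comparison 27 lost their call with it. The poly-A spike-in levels and the ACTB difference above moved with these groups, and the GAPDH difference lay within the range of the other arrays.

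Of 10 NF-kB target genes 7 fell and 2 rose with double siRNA (the same adjusted over the list alone). PLAU was at -0.82 ± 0.06 and NFKBIE, an NF-kB inhibitor gene, at -0.78 ± 0.09, while the adhesion molecule gene VCAM1 was at 1.30 ± 0.15 and IL6 at 0.70 ± 0.08 (SE). Of 8 NF-kB subunits and regulators 6 fell and 1 rose (the same adjusted over the list alone), with RELA at -0.66 ± 0.10, NFKBIA at -0.48 ± 0.07 and CHUK at 1.16 ± 0.14 (SE). Neither list stood apart from the other genes (camera adjusted p = 0.623 and 0.42). Of 13 ETS family genes 6 rose and 4 fell (the same adjusted over the list alone), with ETS1 at 0.53 ± 0.07, ERF at -0.88 ± 0.09, ELF4 at -0.78 ± 0.08 and ELK1 at -0.53 ± 0.07 (SE; camera adjusted p = 0.619). The ETS list had a median of 0.11, which became -0.002 with each array shifted to the same median. PLAU was called with the covariate (-0.66, adjusted p = 0.0413), and the other NF-kB and ETS genes named here were not.

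**Figure D4:**
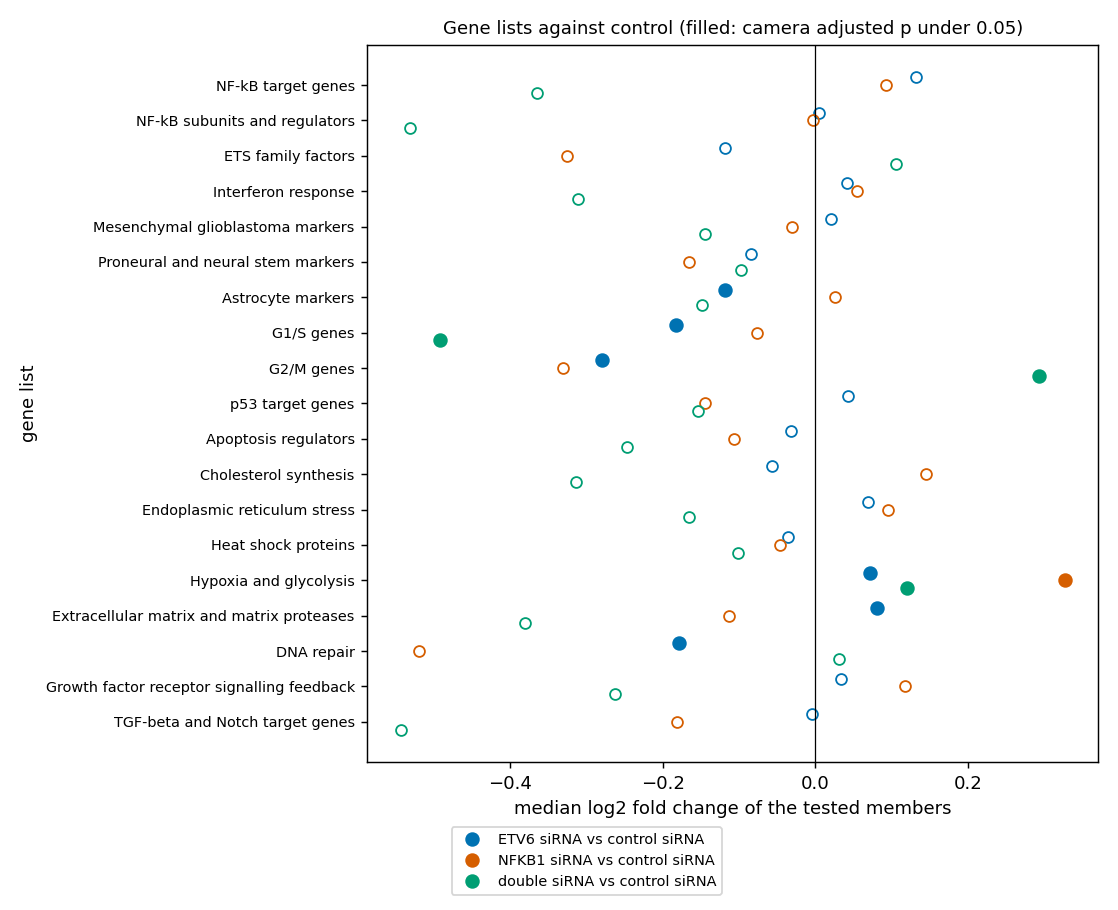
Median log2 fold change of the tested members (x axis) of the 19 tested gene lists (y axis) in the 3 comparisons with control siRNA; filled points mark a camera adjusted p under 0.05 with the preset correlation of 0.01. G2/M genes had a median of -0.28 with ETV6 siRNA and 0.29 with double siRNA, and hypoxia and glycolysis genes had 0.33 with NFKB1 siRNA; no call held with an estimated correlation.

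Double siRNA was also compared with each single siRNA, which asks what 1 siRNA adds in the presence of the other. Against ETV6 siRNA, MRPS12 was 3.55-fold lower (adjusted p = 8.49e-08), MICALL1 3.21-fold, NOL6 3.02-fold and ACTA2, the smooth muscle actin gene, 2.96-fold lower, while OSBPL8 was 5.2-fold, OGFRL1 5.05-fold, SOX2-OT 4.99-fold and PI15 4.89-fold higher. In this comparison 6686 genes differed, 2711 higher and 3975 lower. Of the 8 genes, MRPS12 and ACTA2 were called with the covariate (-1.69, adjusted p = 0.0144, and -1.47, 0.0281), under which 32 genes were called and PI15 was at -0.37. Against NFKB1 siRNA, MEST was 3.36-fold, CITED1 2.48-fold, CDT1 2.29-fold and TRIM16 2.21-fold lower, and OGFRL1 was 7.05-fold, ACSL4 6.99-fold, PI15 6.49-fold and NRIP1 6.04-fold higher. Here 6911 genes differed, 2923 higher and 3988 lower, and 11 were called with the covariate, none of them among these 8; CITED1 was at -1.03 (adjusted p = 0.0519) and PI15 at -0.61. Of 25 G2/M genes 20 were higher and 3 lower with double than with ETV6 siRNA (the same adjusted over the list alone; median 0.88, camera adjusted p = 0.000121, and adjusted p = 0.9 with an estimated correlation). With the covariate the median was 0.312 and 1 gene was called. Of 22 extracellular matrix genes 17 were lower and 1 higher (the same adjusted over the list alone; median -0.47, adjusted p = 0.0329, and adjusted p = 0.9 with an estimated correlation), and with the covariate the median was -0.088 and 0 genes were called.

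Most genes called for the same siRNA with and without the other went opposite ways. Of 743 called both with ETV6 siRNA alone and from NFKB1 siRNA to double siRNA 167 went the same way and 576 the opposite way, and for NFKB1 siRNA 328 and 2372 of 2700 did. With the covariate only 11 and 32 genes were called from NFKB1 and from ETV6 siRNA to double siRNA. Mean positions along its direction were 0.333 for control, 0.105 for ETV6, -0.377 for NFKB1 and 2.089 for double siRNA. Along it the paired changes of either siRNA thus have opposite signs, and its part in these counts was not separated. The change with ETV6 siRNA alone and the change from NFKB1 siRNA to double siRNA were both past 1.5-fold in the same direction for 8 genes, named here after their values were seen. ETV6 itself, CITED1 (-1.19 and -1.31), CXCL8 (-1.13 and -1.14), MEST (-1.07 and -1.75), the immediate early gene EGR1 (-0.73 and -1.0), KLHL7 (-0.72 and -0.65) and CCND1 (-0.61 and -0.90) fell in both, and the selenoprotein gene SELENOP (0.59 and 1.93) rose. For NFKB1 siRNA the corresponding 11 genes were NFKB1, MRPS12 (-1.29 and -1.83), MICALL1 (-1.06 and -1.68), ACTA2 (-0.98 and -1.57), CUX1 (-0.88 and -0.68), NEFL (-0.75 and -1.09), SNN (-0.73 and -1.0), ABHD2 (-0.73 and -0.68) and EPHB1 (-0.71 and -1.16), which fell, and PTPRO (0.77 and 0.91) and the mitochondrial gene ND4 (0.59 and 0.87), which rose. Across all genes the paired changes ran against each other, with a correlation of -0.313 for ETV6 siRNA and -0.606 for NFKB1 siRNA, between comparisons that share no arrays. The first was 0.12 without control siRNA replicate 3 and 0.005 with array weights, and the second was -0.137 with the covariate. Between double siRNA and control, 81 genes were called higher and 109 lower as with ETV6 siRNA, and 351 the opposite way (independent lists 108.4 and 238.5, simulated 3.7 and 4.2; correlation -0.141 against 0.805 simulated; covariance -0.015 against 0.0099). The genes called the same way numbered 440 without control siRNA replicate 3, 102 without ETV6 siRNA replicate 2, 1194 with array weights and 42 with only the groups compared; independent lists were not computed for these. For NFKB1 siRNA the counts were 125, 265 and 2020 (independent 382.4 and 954.2, simulated 4.2 and 4.5; correlation -0.497 against 0.793; covariance -0.0926 against 0.0098). The simulated values again belong to groups without changed genes.

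The interaction asked where double siRNA departed from the sum of both single changes on the log2 scale. HMOX1 departed most among the genes below the sum, at -2.22 ± 0.07 (SE, adjusted p = 2.71e-08): it rose 2.57-fold and 2.21-fold with the single siRNAs and was at 10.25 ± 0.08 with double siRNA against 9.96 ± 0.06 in control cells. HECTD3 (-1.31), TMEM158 (-1.27) and PSKH1 (-1.26) followed, and PI15 (3.89), LRRC58 (3.54), BCAT1 (3.46) and SPOPL (3.42) lay furthest above the sum. ETV6 was 0.81 ± 0.15 above the sum (adjusted p = 0.000358), and NFKB1 was at -0.53 ± 0.25 (adjusted p = 0.061). G2/M genes lay above the sum as a group, 18 above and 5 below of 25 (the same adjusted over the list alone; median 1.20 against -0.18 over all genes, camera adjusted p = 0.00191, and adjusted p = 0.794 with an estimated correlation). With the covariate the list median was 0.334 (camera adjusted p = 0.00265) and none of the 25 genes was called. In all 6698 genes had an interaction, 2834 above and 3864 below. With the covariate 56 genes were called, all 56 the same way as before, and HMOX1 (-1.97, adjusted p = 0.00206) and BCAT1 (1.75, 0.0275) were among them. The other 6 named genes lost their call: PI15 was at 0.274 (adjusted p = 0.843), LRRC58 at 1.617 (0.0546), SPOPL at 0.751 (0.371), HECTD3 at 0.743 (0.358), TMEM158 at -0.783 (0.227) and PSKH1 at -0.415 (0.383).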

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

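Of the tests here, those of RNA or array processing, of mixed RNA, of an effect of both siRNAs, of HMOX1 along the direction shared by control siRNA replicate 3 and the double siRNA arrays, and both of the hypoxia genes were chosen only after the result was seen; those of an array-wide shift, of antioxidant genes and of other splits were chosen before.

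The interaction test called 6698 genes, and 56 with the covariate, in arrays whose RNA or array processing cannot be told apart from the group. The named genes were PI15 (3.89), LRRC58 (3.54), BCAT1 (3.46) and SPOPL (3.42) above the sum of the single changes, HMOX1 (-2.22), HECTD3 (-1.31), TMEM158 (-1.27) and PSKH1 (-1.26) below it, and ETV6 itself (0.81), all on the log2 scale. With the covariate HMOX1 and BCAT1 kept their call and the other 6 named beside ETV6 lost it. G2/M genes had a median interaction of 1.2, and 0.334 with the covariate. Of 100 splits drawn with a fixed seed, 1, the real one, gave as many genes. The highest other split called 4781 genes, which points to a structure of the samples. The 3 double siRNA arrays correlated at 0.997 to 0.998 with each other and at 0.889 to 0.967 with the other arrays. Splits that part them lose that contrast whatever its cause, so the share cannot tell an interaction from processing, and no conclusion is drawn from it. For each of the other 6 comparisons the 10 splits of 3 against 3 are too few for a share under 0.05: 1 split, the real one, gave as many genes (827, 3148, 6274, 6686, 6911 and 2709) and the highest other gave 0. Among 1293 probe sets with no listed gene, which the comparisons left out, 174 were called over 2-fold higher with double siRNA and 5 lower, 13.5% higher against 10.9% of 17313 listed probe sets.

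The double siRNA arrays stood apart from all others across most genes. An array-wide shift in level is argued against, since at least 6392 genes were still called against control with each array shifted to the same median or after quantile normalization. A difference in RNA or array processing cannot be told apart from the group, as the poly-A spike-in levels of the double siRNA arrays lay outside those of all others (exact permutation p = 0.00455), while the 3' minus 5' difference of GAPDH lay within their range (exact permutation p = 0.341). Mixing of double siRNA RNA into control siRNA replicate 3 may explain why that array shares the direction: the median mixed share over 35 genes that follow an siRNA was 28.6% (quartiles 14.2 and 45.3) against 30.8% fitted over all genes, ETV6 gave 38.9% and 33 of the 35 genes lay above 0, but a log2 slope left as little residual (142.2 against 145.2) and NFKB1 gave -51.7%, so this stays open. An effect of knocking down both genes stays open too, with 314 genes called with the covariate, fewer than in either single comparison with it (1263 and 1617) and with larger errors. It cannot be told apart from an effect of total siRNA, which the labels do not say was equal between groups.

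HMOX1 was higher with each single siRNA (1.36 and 1.15 on the log2 scale) and less so, by 0.29 ± 0.05 (SE), with both. The direction shared by control siRNA replicate 3 and the double siRNA arrays is argued against as the whole cause only if HMOX1 changes linearly along it. The interaction was then -1.97 ± 0.20 (SE, limma, adjusted p = 0.00206) with the covariate. The slope of the covariate rests largely on control siRNA replicate 3, at 1, and the double siRNA arrays lie beyond it, at 2.051 to 2.141. A rise of antioxidant response genes as large as that of HMOX1 is argued against: the larger camera p of that list without HMOX1 in the single comparisons was 0.366, with medians of 0.035 and -0.004 over 17 tested genes, of which 2 rose and 1 fell with ETV6 siRNA and 5 rose and 2 fell with NFKB1 siRNA, the highest being GCLM at 0.41 and MAFG at 0.435; a smaller rise of some stays open. Differences in RNA processing of the double siRNA arrays that do not follow that direction were not tested for HMOX1, so a response to each siRNA alone that is smaller with both is at most a hypothesis.

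Of 22 hypoxia and glycolysis genes 15 rose with NFKB1 siRNA and none fell (camera adjusted p = 8.3e-08, and adjusted p = 0.139 with an estimated correlation, the only alternative in which the list was not called). The direction shared by control siRNA replicate 3 and the double siRNA arrays is argued against as their cause, since the median was 0.357 with the covariate and 0.33 without it. Whether NFKB1 siRNA has this effect whatever the other siRNA stays open: the median of double against ETV6 siRNA was -0.034 with the covariate and -0.045 without it, but the mean was 0.21 without it and 0.046 ± 0.087 (SE) with it. The mean interaction of the list was -0.137 ± 0.048 (SE, median -0.347, camera adjusted p = 0.474) without the covariate and -0.36 ± 0.119 (SE, median -0.26, adjusted p = 0.00286) with it, the only alternative of 24 in which it was called (up to 0.794 with an estimated correlation).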

How the results depend on the processing

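The covariate and the pair of arrays left out together were tests chosen after seeing the data; all others were planned. Over all alternatives the 22 main results, which include counts of genes and correlations, were labelled the same in 468 values. They became weaker in 31, stronger in 24, lost or reversed their sign in 3 and moved in 1. For counts the label allows a different number, such as 959 against 827 genes for ETV6 siRNA without control siRNA replicate 3. For levels called in neither fit it does not mean that the sign was kept. NFKB1 in double against NFKB1 siRNA was at -0.036, and at 0.147 without NFKB1 siRNA replicate 1. For gene lists the counts were 1821 the same, 63 weaker and 73 stronger. These include fry, which gave 37, 1 and 38 of them and tests each list against no change. For named genes they were 3386 the same, 127 weaker, 19 stronger and 4 reversed. CHUK with ETV6 siRNA, at -0.122 and not called, ranged from -0.285 to 0.173 and is not among the 4 reversed.

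With the covariate the counts of changed genes were 1263 for ETV6 siRNA against control, 1617 for NFKB1 siRNA, 314 for double siRNA, 32 for double against ETV6 siRNA, 11 for double against NFKB1 siRNA and 56 for the interaction. With array weights they were 2342 for ETV6 siRNA and 4333 for ETV6 against NFKB1 siRNA, and with only the groups compared, which leaves fewer samples, 187 for ETV6 siRNA and 1855 for NFKB1 siRNA. Testing every probe set, which tests more features, gave 5136 for NFKB1 siRNA, 10299, 11031 and 11478 for double siRNA against control, ETV6 and NFKB1 siRNA, 4285 for ETV6 against NFKB1 siRNA and 11051 for the interaction. The 50th percentile filter, which tests fewer genes, gave 4426, 4563 and 4418 for double against ETV6 siRNA, double against NFKB1 siRNA and the interaction. Without 1 array the counts ranged from 436 to 959 for ETV6 siRNA, 2351 to 3647 for NFKB1 siRNA, 5952 to 6413 for double siRNA, 6418 to 6757 and 6728 to 6974 for double against ETV6 and NFKB1 siRNA, 1665 to 3654 for ETV6 against NFKB1 siRNA, and 6516 to 6711 for the interaction. With a replicate block they were 760, 3195, 6283, 6687, 6906, 2717 and 6682; the replicate numbers do not pair the arrays, as 5 of 18 same-numbered pairs of deviations correlated over 0.1 (from -0.516 to 0.482) and 2 of 12 arrays correlated best with their own number.

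ETV6 with NFKB1 siRNA was called lower with array weights (-0.296), the covariate (-0.44), and control siRNA replicate 3 or both doubted arrays left out (-0.324), and ranged from -0.324 to -0.1 without 1 array. For double against NFKB1 siRNA it was -0.415, not called, with the covariate. NFKB1 with ETV6 siRNA was called higher with shifted medians (0.506), quantile normalization (0.506), array weights (0.573), only the groups compared (0.498) and NFKB1 siRNA replicate 3 left out (0.498), and was 0.618, not called, with both doubted arrays left out. NFKB1 with NFKB1 siRNA was -0.729 with only the groups compared (limma, adjusted p = 0.0524) and -0.564 with the covariate, neither called. With the covariate NFKB1 was at -1.173 for double siRNA against control and -1.724 for double against ETV6 siRNA, neither called. For double against NFKB1 siRNA it was called lower, at -0.231, with array weights. The other ranges without 1 array were -2.293 to -2.069, -1.658 to -1.433, 0.573 to 0.672 and -1.371 to -1.296 for ETV6 (ETV6 and double siRNA against control, double against ETV6 and NFKB1 siRNA). For NFKB1 they were 0.451 to 0.583 and -0.912 to -0.462 (ETV6 and NFKB1 siRNA against control), -0.813 to -0.68, -1.298 to -1.237, and -0.303 to 0.147 (double siRNA against control, ETV6 and NFKB1 siRNA).

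The correlation of the ETV6 siRNA changes with and without NFKB1 siRNA was near 0 with array weights (0.005) and the covariate (0) and reversed to 0.12 without control siRNA replicate 3 (-0.507 to 0.12 without 1 array). That for NFKB1 siRNA was -0.137 with the covariate and -0.678 to -0.417 without 1 array. With the covariate PI15 reversed to -0.374 and -0.612 (double against ETV6 and NFKB1 siRNA), NRIP1 to -0.411 (double against NFKB1 siRNA) and HECTD3 to 0.743 (interaction), none past the threshold. Genes called the same way with ETV6 and NFKB1 siRNA numbered 1144 with array weights and 115 with only the groups compared (263 to 641 without 1 array), with ETV6 and double siRNA 1194, 42 and, with the covariate, 107 (102 to 440), and with NFKB1 and double siRNA 915, 227 and 67 (271 to 483). Where no reason is given, the cause was not tested. How far signals stand over background is not given, so what dim genes such as NFKB1 could show is limited to an unknown degree.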

Other observations

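The genes called with the covariate were chosen for description, and their tests run, only after the result was seen; the gene lists were fixed before.

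The lists that did not stand apart against control are given as camera adjusted p for ETV6, NFKB1 and double siRNA in turn. They were 0.424, 0.748 and 0.901 for interferon response, 0.424, 0.536 and 0.646 for mesenchymal glioblastoma markers, 0.517, 0.123 and 0.901 for proneural and neural stem markers, and 0.401, 0.536 and 0.761 for p53 target genes. They were 0.557, 0.748 and 0.901 for apoptosis regulators, 0.424, 0.074 and 0.901 for cholesterol synthesis, 0.095, 0.28 and 0.932 for endoplasmic reticulum stress, and 0.126, 0.0978 and 0.901 for heat shock proteins. They were 0.625, 0.28 and 0.619 for growth factor receptor signalling feedback and 0.557, 0.191 and 0.3 for TGF-beta and Notch target genes. Astrocyte markers gave 0.816 and 0.901 with NFKB1 and double siRNA. With NFKB1 siRNA, DNA repair genes gave 0.074, extracellular matrix genes 0.074, G1/S genes 0.0978 and G2/M genes 0.182, and with double siRNA DNA repair gave 0.556 and extracellular matrix 0.0793. Median and mean differed in sign for growth factor feedback with ETV6 siRNA, for interferon response and astrocyte markers with NFKB1 siRNA, and for p53 targets, apoptosis regulators and endoplasmic reticulum stress with double siRNA. The test ran against both for NF-kB subunits and regulators with NFKB1 siRNA and for proneural markers with double siRNA.

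Some of these lists were called in a few of 25 alternatives, given here with the range of the adjusted p. With ETV6 siRNA this was endoplasmic reticulum stress in 1 (0.042 to 0.366). With NFKB1 siRNA it was cholesterol synthesis in 6 (0.000923 to 0.324), extracellular matrix in 5 (0.000147 to 0.755), DNA repair in 4 (0.000923 to 0.645), heat shock proteins in 2 (0.00138 to 0.645), G1/S in 2 (0.0113 to 0.755), TGF-beta and Notch targets in 2 (0.0147 to 0.742) and proneural markers in 1 (0.0474 to 0.645). With double siRNA it was extracellular matrix in 3 (0.00123 to 0.922) and TGF-beta and Notch targets in 2 (0.00981 to 0.922). The other lists of the paragraph above were called in none.

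Some single members of these lists changed, and they are named after their values were seen. MET, the receptor of hepatocyte growth factor, was at -0.67 with ETV6 siRNA and -1.08 with NFKB1 siRNA. CHI3L1 was at 0.68 and -0.47, and PDGFRA, a growth factor receptor gene of proneural tumours, at 0.41 and -0.82. The chaperone gene HSP90AA1 was at -1.0 with NFKB1 siRNA.

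With the covariate 11 genes differed between double and NFKB1 siRNA. GLDN (1.68), NUDT21 (1.37), VKORC1L1 (1.37), OGA (1.30), MAP3K5 (1.20), SIRT1 (1.17), RBMS1 (1.05), POPDC1 (1.01) and PLK2 (1.01) were higher, and PIK3C2B (-1.36) and RCCD1 (-1.29) were lower, with adjusted p between 0.0226 and 0.0473.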
